A study of Mus musculus with 12 samples.

How the data were processed

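Gene expression was measured by RNA sequencing in 12 libraries of mouse splenic B cells. Per the labels, B cells were enriched with a magnetic kit and sorted by flow cytometry into marginal zone (MZ) cells, with high CD21 and no CD23, and follicular (FO) cells, with CD21 and CD23. The labels give both gates as positive for B220 and CD93. Groups were taken from the genotype and cell type in the labels: 4 Zfp36l1-deficient MZ libraries (replicates 1, 2, 7 and 8; Zfp36l1fl/flERT2cre/+), 4 control MZ libraries (replicates 3, 4, 5 and 6; ERT2cre/ERT2cre) and 4 FO libraries (replicates 3, 4, 7 and 8; Zfp36l1fl/fl cre-). Deficient and control MZ cells therefore differ in the floxed allele and in the number of ERT2cre copies. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. No identical library columns were found (0), and every pair of replicates differed by more than sampling noise (chi-square per gene 5.78 to 48.6).

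Per the labels' design text, MZ libraries were made from 5 ng of RNA with a Clontech SMARTer kit and read as 100 bp pairs, and FO libraries with a stranded TruSeq mRNA kit and read as 100 bp single ends. The extraction protocol in the labels names the SMARTer kit for all samples, so the FO kit rests on the design text alone. Per the submitters' processing notes, Trim Galore, TopHat2 2.0.12, HTSeq and DESeq2 1.10.1 were used with build GRCm38. The annotation release, the counting mode and the strand setting are not given in the sources used here. The deposited raw counts are whole numbers per Ensembl gene, with 1 column per library and no pooling. The deposited normalised signal equals the raw count divided by 1 factor per library, between 0.842 and 1.15. It was used only to find those factors, and the mean signal in the authors' result tables was not used for any test. The authors' log2 fold changes and the authors' adjusted p-values come from their 2 deposited DESeq2 tables, and whether the fold changes were shrunk is not given in the sources used here.

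The depth was 28938453 to 40664963 counts per library. The table holds 43629 genes, of which 19338 had no count in any library. Of the gene IDs, 42548 matched the GENCODE M21 annotation (Ensembl 96, the same build), which gave symbols, coordinates, biotypes and 3′ untranslated regions (UTRs). No line of the table named anything but a gene (0).

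Differential expression was tested on the raw counts with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, edgeR's default filter on low counts by group and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called changed. Each comparison was fitted on its own 8 libraries, because the FO libraries were made and read in another way. The biological coefficient of variation was 0.123 among MZ libraries and 0.104 in the fit of control MZ and FO libraries. Levels are TMM-scaled counts over the library total (CPM) with the SD over 4 libraries. Fold changes are log2 values with their standard error (SE).

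Gene lists were tested with camera at a preset correlation of 0.01 between genes, again with a correlation estimated per list, and with fry. The 34 lists (890 symbols for pathways, B cell subsets and other splenic cells) were fixed before the data were examined. So were the tests of the comparisons, the groups, the rule for named genes and all alternatives but 6. Of the symbols, 4 had no match. Lists with fewer than 5 tested members were counted but not tested. The share of genes with the AU-rich heptamer TATTTAT in their longest annotated 3′ UTR was compared with Fisher's exact test and with a logistic model that included UTR length and mean level.

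The genes named are those fixed in advance (Zfp36l1, Zfp36, Zfp36l2, Klf2, Irf8, Notch2, Cr2, Fcer2a and Cd1d1), the 8 largest called changes in each direction and up to 4 members of each described list with the smallest p. The largest changes were limited to genes with a mean log2 CPM of at least 3, groups that do not overlap, and symbols that are not predicted, immunoglobulin, T cell receptor or sex-linked genes. For genes called in both comparisons, up to 6 per combination of directions qualified. In the comparison of deficient and control cells, Rasgrp2, Tnfaip3, Il5ra, Srgap3, Hdhd5, Myof, Itgb7, Ccr7, Id2, Birc5, Kif11 and Cdc6 lie outside this rule and were chosen after their values were seen. The same holds for Rpl13, Rpl24, Trim30a, Fas, Efnb1, Myb and Adgre1 in the comparison of control MZ and FO cells. Some genes that qualified are not reported here.

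The procedure was tested on simulated counts drawn from the means and depths of the real libraries. In the deficient against control design (13792 genes tested), 58.2% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered. In the control MZ against FO design (13556 genes), these shares were 62.7%, 76.1% and 98.5%. False calls made up 6.21% and 5.39% of the calls.

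Where every library of a group had a count of 0, the fold change is given as a lower limit against 3 counts over the group. A fold against 1 to 3 counts is given with its 95% counting interval. Such limits and intervals cover counting error only. Alternatives covered DESeq2 1.42.0, voom in limma 3.58.1, other scaling factors, other filters on low counts, a test against a fold change of 1.5, an offset for GC content and gene length, and all 12 libraries in 1 fit. Each replicate was also left out in turn, and the replicate number was tried as a block. Bar the 6 added later, these were set before any value was seen.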

Results

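MZ B cells respond quickly to blood-borne antigens from the edge of the splenic follicle, whereas FO B cells circulate through the follicles. To ask how the RNA-binding protein Zfp36l1, which speeds the decay of mRNAs with AU-rich elements, shapes gene expression in MZ B cells, RNA from Zfp36l1-deficient and control MZ B cells was sequenced alongside RNA from FO B cells, with 4 libraries in each group. Zfp36l1 mRNA fell in deficient MZ cells from 127 ± 6.78 to 32.0 ± 7.03 CPM (mean ± SD, n = 4 and 4), a log2 change of −1.98 (SE 0.12; edgeR quasi-likelihood, adjusted p = 4.18e-07). Deficient replicates 1, 2, 7 and 8 held 23.5, 34.0, 30.3 and 40.3 CPM, and control replicates 3, 4, 5 and 6 held 126, 119, 125 and 136. None of the 70 possible orderings of the 8 libraries separated them further (exact permutation p = 0.0286, the smallest possible). Of the exon bases of Zfp36l1, 55.9% lie under exons of the other strand. In the authors' table the log2 change is −1.64 (DESeq2, adjusted p = 1.2e-49).

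Loss of Zfp36l1 went along with higher Klf2, which encodes a transcription factor that restrains MZ B cell formation, and higher Vim, which encodes the intermediate filament protein vimentin. Klf2 rose from 43.6 ± 7.43 to 159 ± 6.39 CPM, a log2 change of 1.87 (SE 0.10; edgeR quasi-likelihood, adjusted p = 1.11e-07), and Vim rose from 12.1 ± 0.789 to 43.7 ± 6.35, a log2 change of 1.85 (SE 0.11; edgeR quasi-likelihood, adjusted p = 2e-07). The family member Zfp36l2 rose (log2 1.13, SE 0.16; edgeR quasi-likelihood, adjusted p = 0.00173), while no change in Zfp36 was called (log2 0.14, SE 0.07; edgeR quasi-likelihood, adjusted p = 0.296). The transcription factor Irf8 rose (log2 0.37, SE 0.08; edgeR quasi-likelihood, adjusted p = 0.0146), and the related factor Irf4, which drives plasma cell differentiation, fell (log2 −0.52, SE 0.07; edgeR quasi-likelihood, adjusted p = 0.000744). Notch2, the receptor that directs MZ B cell fate, was not called (log2 0.08, SE 0.11; edgeR quasi-likelihood, adjusted p = 0.72). The genes of the sort markers, Cr2 for CD21 (log2 −0.26, SE 0.08) and Fcer2a for CD23 (log2 −0.21, SE 0.32), were not called either (edgeR quasi-likelihood, adjusted p = 0.0856 and 0.775).

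**Figure D1:**
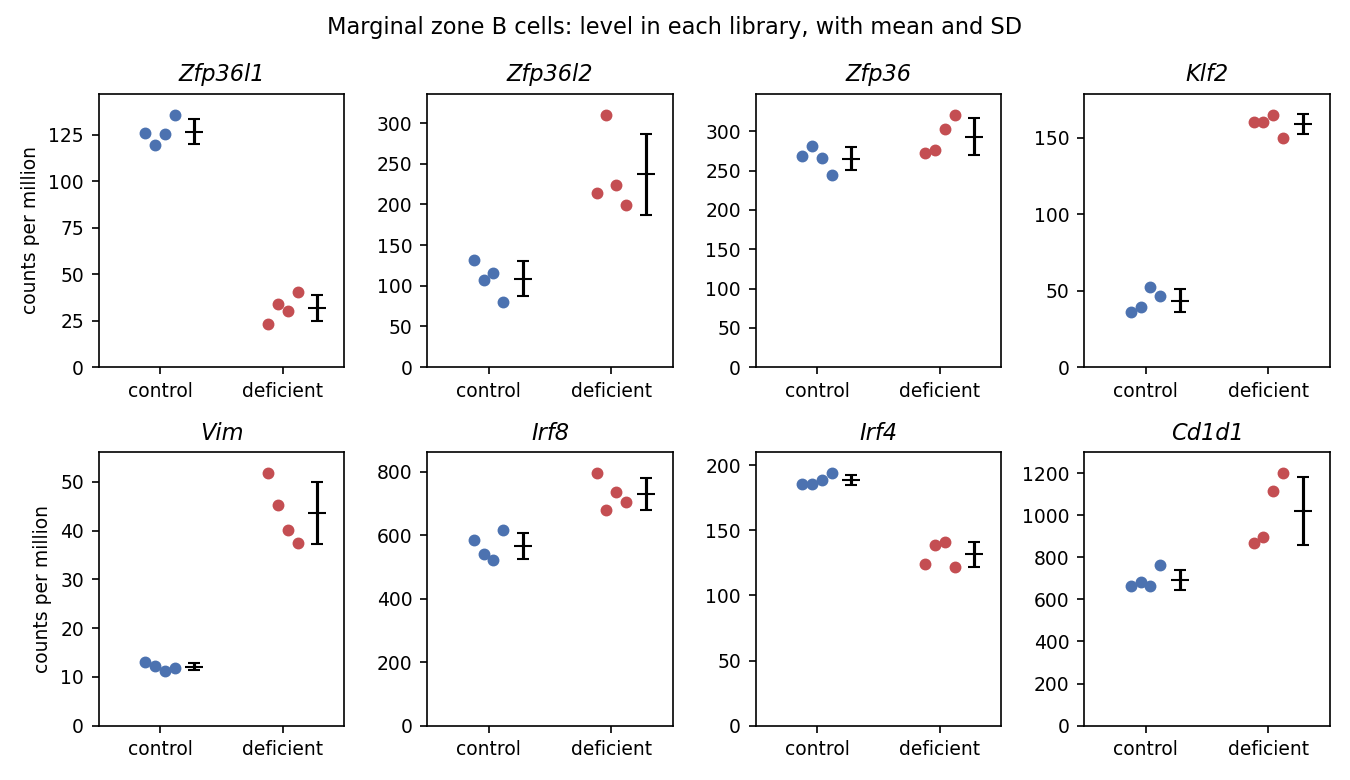
Levels of 8 genes in each control and Zfp36l1-deficient MZ library, in CPM. Bars show the mean and SD of 4 libraries.

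Across the transcriptome, 526 of 13987 tested genes changed (edgeR quasi-likelihood, adjusted p < 0.05), 322 of them higher and 204 lower in deficient cells. None of the other 34 ways to split these 8 libraries into groups of 4 called more than 1 gene. Chance is therefore unlikely for this count, but 1 of 35 splits is the smallest share possible. The other splits also mix the groups, which adds any real difference to the spread within them. In the authors' table, 1052 genes have an adjusted p under 0.05 (568 higher, 484 lower), and 522 of the 526 genes are among them in the same direction. Under the rule for named genes (mean log2 CPM of at least 3, groups that do not overlap), Gt(ROSA)26Sor rose most, from 0.624 ± 0.235 to 18.7 ± 2.35 CPM (log2 4.88, SE 0.21). It is a non-coding gene at a locus often used for transgenes. Grm6 came next (log2 3.10, SE 0.23). Plxnd1, which encodes a semaphorin receptor, rose from 13.3 ± 3.58 to 86.7 ± 14.7 (log2 2.71, SE 0.17). Lyrm7 (log2 1.90, SE 0.19), the actin-bundling gene Fscn1 (log2 1.72, SE 0.35) and the chemokine receptor Cxcr4 (log2 1.30, SE 0.19) rose as well. Under the same rule, which leaves out genes at lower levels, the largest decreases after Zfp36l1 were in Osgin1, from 10.9 ± 1.27 to 5.46 ± 1.26 CPM, the nuclear envelope gene Sun2 (log2 −0.96, SE 0.18), Cecr2 (log2 −0.95, SE 0.16) and the integrin gene Itgb3 (log2 −0.89, SE 0.13). Antxr2 (log2 −0.87, SE 0.12), Zkscan17 (log2 −0.80, SE 0.09) and Man1b1 (log2 −0.80, SE 0.16) also fell. The call of Irf8 was lost without control replicate 4, that of Sun2 without deficient replicate 1, and that of Fscn1 without deficient replicate 1 or control replicate 3, 4 or 5.

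Of 16 tested genes that mark FO B cells, 7 rose in deficient MZ cells, 0 fell and 9 were not called. The list was called at the preset correlation (camera, adjusted p = 1.86e-11) but not with an estimated correlation (camera, adjusted p = 0.131). Adjusted over the list alone, 8 rose and 0 fell. Besides Klf2 and Cxcr4, those that rose included Cd55 (log2 0.60, SE 0.09), the Fc receptor gene Fcgrt (log2 1.12, SE 0.18), the integrin gene Itgb7 (log2 0.45, SE 0.11) and the chemokine receptor gene Ccr7 (log2 0.36, SE 0.08). Fcer2a, whose product CD23 the MZ gate excludes, was among those not called. For 13 members lower in control MZ than in FO cells, Klf2 left out, the median rise was 0.0574 of the difference between these cells. Only 3 of the 13 rose by over 0.1 of it. This list's p was smallest in the real split (6.43e-13, next 1.59e-10), but in 7 of the 35 splits some list stood as far below its p in all other splits, so chance cannot be excluded. Of 20 MZ B cell genes, 3 rose and 2 fell, and the list was not called (camera, adjusted p = 0.805), with 4 higher and 4 lower adjusted over the list alone. Those that rose were Cd1d1, which presents lipids (log2 0.56, SE 0.10; edgeR quasi-likelihood, adjusted p = 0.00742), Asb2 (log2 0.71, SE 0.10) and the RNA sensor Tlr3 (log2 0.56, SE 0.08). The Notch regulator Dtx1 fell (log2 −0.40, SE 0.08; edgeR quasi-likelihood, adjusted p = 0.01), as did Myof (log2 −0.34, SE 0.09; edgeR quasi-likelihood, adjusted p = 0.0498). In the Notch pathway, 1 of 34 genes rose, the target Hes5 (log2 0.46, SE 0.10), and 2 fell, Dtx1 and Dtx4 (log2 −0.51, SE 0.13). Without single libraries some calls were lost: Itgb7 (deficient replicates 1, 2 or 8, control replicates 5 or 6), Ccr7 (control replicates 3, 4 or 6), Hes5 (control replicates 3, 4 or 6, deficient replicate 8) and Dtx4 (deficient replicates 1, 7 or 8, control replicates 4 or 6). The call of Myof was kept only without deficient replicate 7, and it was lost with other scaling factors.

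Cell cycle genes were also higher: 7 of 39 rose and 0 fell (camera, adjusted p = 1.2e-09; adjusted p = 0.148 with an estimated correlation), or 16 and 0 adjusted over the list alone. Ube2c, which marks mitotic proteins for degradation, rose most (log2 1.68, SE 0.25), followed by Cdc6, which licenses replication origins (log2 1.62, SE 0.35), the kinase gene Cdk1 (log2 1.21, SE 0.21), Birc5 (log2 1.04, SE 0.26), the spindle motor gene Kif11 (log2 0.94, SE 0.24), Ccna2 (log2 0.93, SE 0.19) and the nucleotide synthesis gene Rrm2 (log2 0.83, SE 0.16). Of the 35 splits, 5 gave the list as small a p (real 8.28e-11, smallest other 7.08e-13), so chance cannot be excluded. Replication-dependent histone genes rose in 2 of 17 cases (camera, adjusted p = 0.000853; adjusted p = 0.131 with an estimated correlation), Hist1h2bc (log2 0.73, SE 0.13) and Hist1h1c (log2 0.53, SE 0.12), and 2 of the 35 splits gave this list as small a p, so chance cannot be excluded. Calls lost without single libraries were those of Ccna2 (control replicate 4), Cdc6 (control replicates 3 or 4, deficient replicate 8), Hist1h1c (control replicates 3 or 6, deficient replicate 7) and Birc5 (control replicates 3, 4 or 5, deficient replicates 1, 7 or 8). That of Kif11 was kept only without deficient replicate 7. In the cell cycle list, 4, 3 and 4 genes rose without control replicate 3, control replicate 4 and deficient replicate 8.

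Among published targets of the Zfp36 family, 5 of 26 rose and 0 fell (camera, adjusted p = 0.00198; adjusted p = 0.131 with an estimated correlation), or 7 and 1 adjusted over the list alone. They were the growth regulator Myc (log2 0.70, SE 0.11), the cell cycle drivers Ccnd3 (log2 0.64, SE 0.08) and E2f2 (log2 0.60, SE 0.07), the survival kinase Pim1 (log2 0.87, SE 0.17) and the phosphatase gene Dusp1 (log2 0.66, SE 0.12). The p of this list was smallest in the real split (0.000479, next 0.00356), but in 9 of the 35 splits some list stood as far below its p in all other splits, so chance cannot be excluded. Of 25 immediate-early genes, 4 rose and 1 fell (camera, adjusted p = 0.0045; adjusted p = 0.3 with an estimated correlation). With Myc and Dusp1, Dusp5 (log2 0.81, SE 0.16) and Jund (log2 0.45, SE 0.08) rose, and Tnfaip3, which dampens NF-κB signalling, fell (log2 −0.43, SE 0.10). For this list 2 of the 35 splits gave as small a p, so chance cannot be excluded. Dusp5 was not called without control replicate 4 or deficient replicate 8, nor Tnfaip3 without control replicates 3 or 4 or deficient replicate 8.

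The AU-rich heptamer TATTTAT lay in the 3′ UTR of 102 of 288 genes that rose (35.4%) and of 3238 of 11114 other tested genes (29.1%). The odds ratio was 1.33 (95% interval 1.03 to 1.71, Fisher's exact p = 0.0256), or 1.68 when UTR length and mean level were included (logistic model, p = 0.000241). Of the 21 heptamers with 2 A and 5 T, none had a higher odds ratio. Genes that fell in deficient cells carried the motif at 1.08 times the odds of other genes (Fisher's exact p = 0.637). Leaving out 1 library gave odds ratios from 1.22 to 1.44 and exact p from 0.00641 to 0.177. In the logistic model these odds ratios ran from 1.47 to 1.79, with p from 0.000107 to 0.0464. In a separate list, Zbtb32 (log2 1.90, SE 0.25), Bhlhe40 (log2 1.25, SE 0.10) and Nid1 (log2 0.76, SE 0.10) among 10 B-1 cell markers rose (camera, adjusted p = 1.65e-05; adjusted p = 0.131 with an estimated correlation), and as 4 of the 35 splits gave that list as small a p, chance cannot be excluded.

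In the list of migration receptors and adhesion genes, 7 of 66 rose, with Cd81 (log2 0.92, SE 0.11) and the sphingosine receptor gene S1pr4 (log2 0.57, SE 0.08) among them, and 1 fell (Itgb3), but the list was not called (camera, adjusted p = 0.0511). Of 41 B cell transcription factors, 4 rose, Klf2, Irf8, Pou2f2 (log2 0.41, SE 0.07) and Id2 (log2 0.39, SE 0.09), and 1 fell (Irf4). Id2 was not called without deficient replicates 1 or 2 or control replicates 3, 4 or 6, 2 factors rose without control replicate 4, and 2 factors as well as 2 migration genes fell without deficient replicates 1 or 7. Rasgrp2, an activator of integrin signalling, rose (log2 0.46, SE 0.07). In Toll-like receptor signalling, Tlr3 rose, while Tlr4 (log2 −0.41, SE 0.08), Tlr6 (log2 −0.66, SE 0.15) and the NF-κB inhibitor gene Nfkbie (log2 −0.25, SE 0.06) fell. Tlr6 was not called without deficient replicates 2 or 8 or control replicates 3, 4 or 6, and the call of Nfkbie was kept only without deficient replicate 1. Of 60 nuclear genes of oxidative phosphorylation, 2 rose, Cox7a2 (log2 0.56, SE 0.11) and Uqcrq (log2 0.64, SE 0.15) (camera, adjusted p = 3.71e-08; adjusted p = 0.601 with an estimated correlation). Of 75 ribosomal protein genes 1 rose, Rpl5 (log2 0.45, SE 0.09) (camera, adjusted p = 1.68e-07; adjusted p = 0.601 with an estimated correlation). As small a p came from 15 and 16 of the 35 splits for these lists, so chance cannot be excluded. Without deficient replicate 7, 5 genes of oxidative phosphorylation rose. Uqcrq was not called without control replicates 3, 4 or 6 or deficient replicate 8, nor Rpl5 without control replicate 6.

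Few markers of other cells changed. The haemoglobin gene Hbb-bt rose (log2 1.44, SE 0.37), 1 of 10 erythroid markers (camera, adjusted p = 0.00688; adjusted p = 0.487 with an estimated correlation). Its call was kept only without control replicate 5, where 4 erythroid markers rose, and 0 rose without any other library. As 6 of the 35 splits gave the list as small a p, chance cannot be excluded. Of 7 T cell markers 2 rose, Cd8a from 0.512 to 2.10 CPM (log2 2.04, SE 0.42) and Tcf7 (log2 2.46, SE 0.53), the latter not called without control replicates 3 or 4 or deficient replicate 8. Of 20 macrophage markers 1 rose, Adgre1 (log2 1.37, SE 0.28), and 0 of 9 dendritic cell and 0 of 11 platelet markers changed, though 1 dendritic cell marker rose without control replicate 3, 4, 5 or 6 or deficient replicate 8. In all, 9 of 29 lists were called, and 11 of the 35 splits called as many (highest other 12), so chance cannot be excluded for the number of lists.

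**Figure D2:**
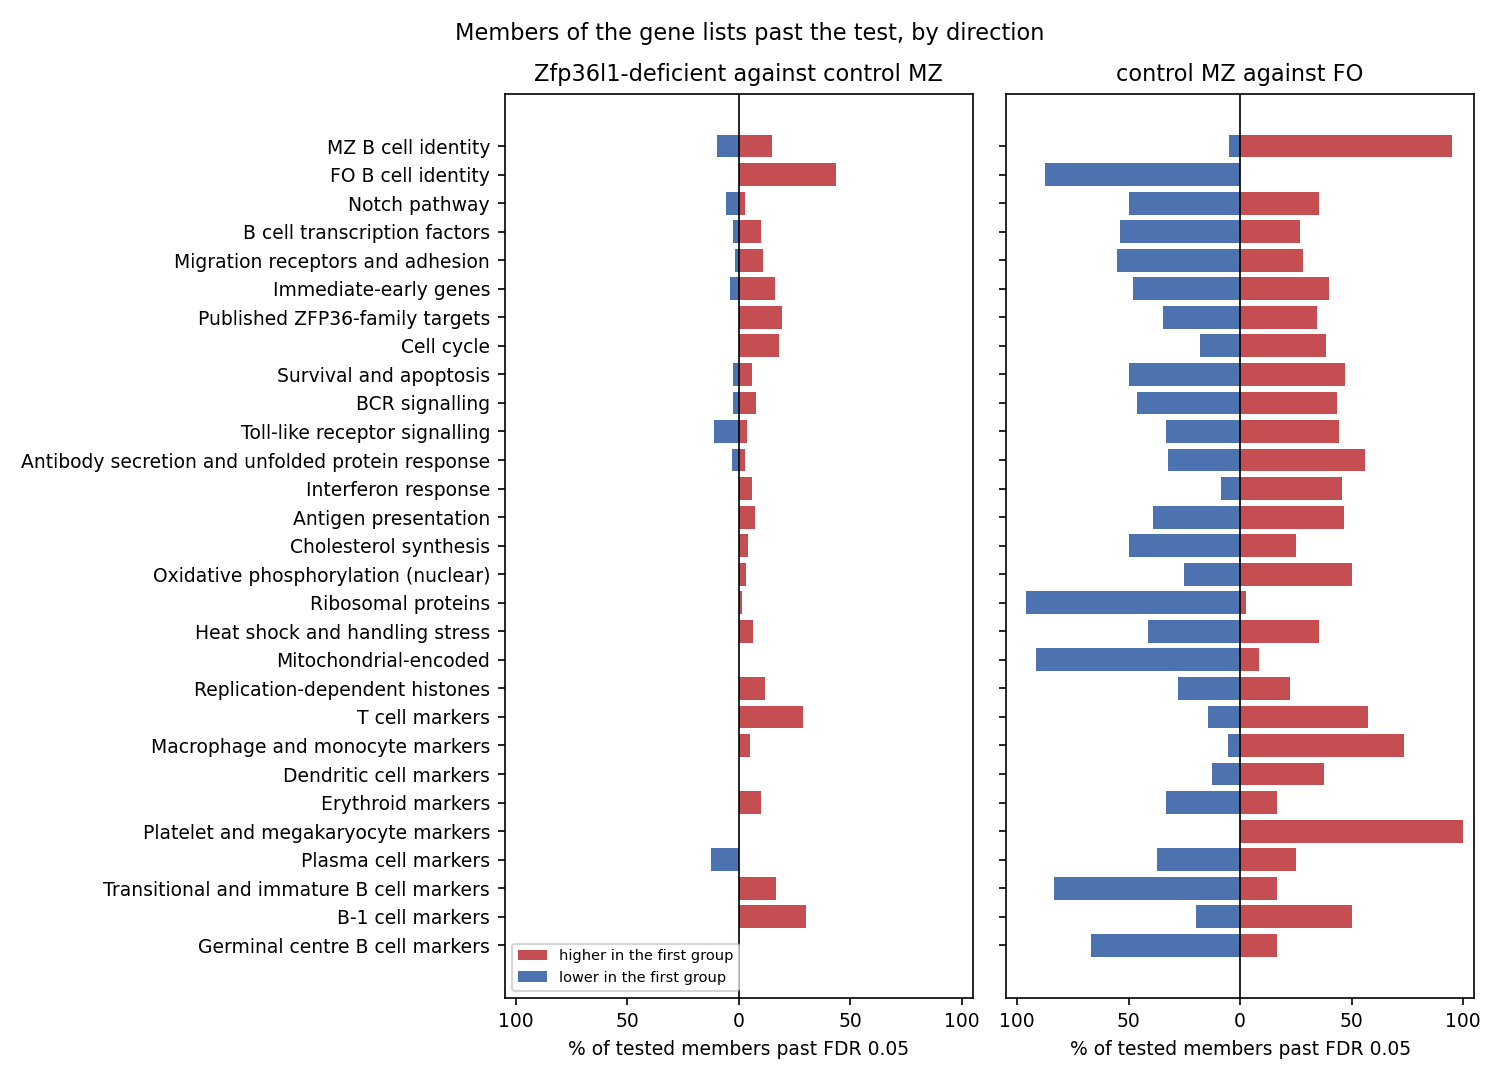
Share of tested members of each gene list that were higher or lower in deficient against control MZ cells and in control MZ against FO cells. Lists with at least 5 tested members are drawn.

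Genes near Zfp36l1 on chromosome 12 were not called more often than others: 7 of 191 within 20 Mb (3.66%) against 3.75% elsewhere (odds ratio 0.977, 95% interval 0.385 to 2.07, Fisher's exact p = 1). That test pooled both directions. All 7 were lower in deficient cells, against 204 of all 526 called genes, and the nearest lies 0.01 Mb from Zfp36l1. Tmed10 was among them (log2 −0.58, SE 0.07). Whether lower calls alone were more frequent there was not tested. Around Gt(ROSA)26Sor on chromosome 6, examined because that gene rose most under the rule for named genes, 17 of 191 genes were called (8.9%) against 3.68% elsewhere. The odds ratio was 2.56 (95% interval 1.45 to 4.26, Fisher's exact p = 0.000853), and 28 of 12387 windows elsewhere (0.23%) had as high a share. These windows were placed around single genes and overlap widely, so they are not independent and their share is no p-value. Of the 17, 10 rose and 7 fell. Those that rose included Plxnd1, Bhlhe40, the receptor gene Il5ra (log2 1.19, SE 0.22), Srgap3 (log2 1.18, SE 0.22) and Hdhd5 (log2 0.68, SE 0.08), and Cecr2 was among those that fell.

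**Figure D3:**
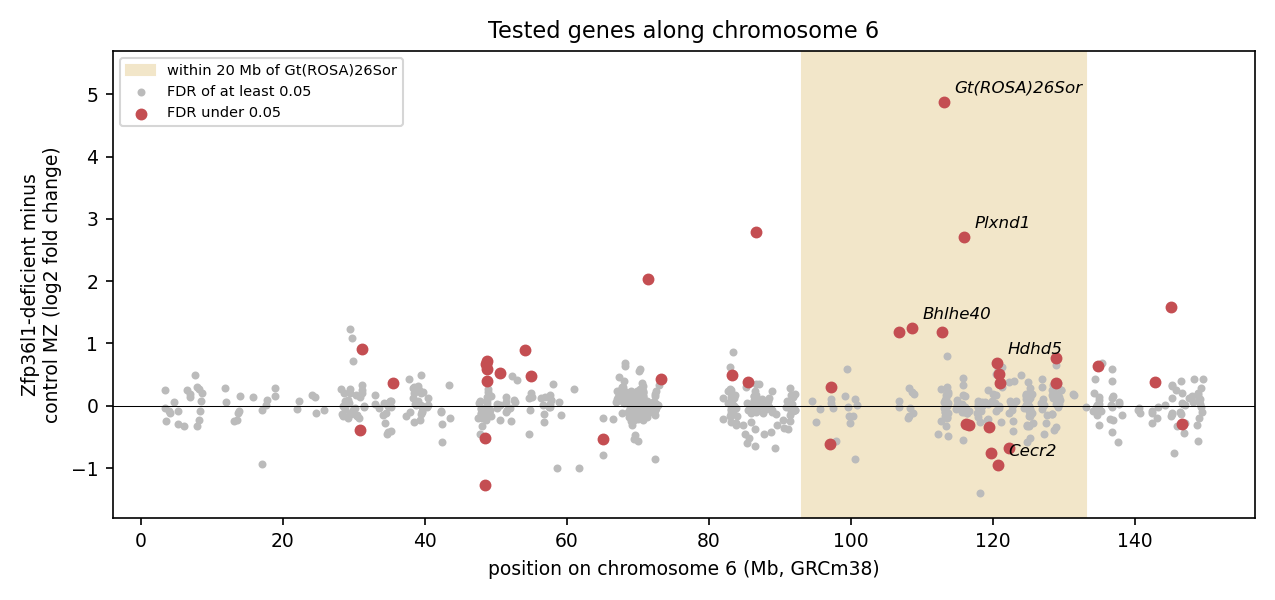
Log2 change between deficient and control MZ cells of 700 tested genes along chromosome 6, with 40 called genes marked. The shaded band spans 20 Mb on each side of Gt(ROSA)26Sor.

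Control MZ B cells differed from FO B cells at the genes of MZ fate. S1pr3, which encodes a receptor for sphingosine 1-phosphate, stood at 546 ± 46.8 against 7.18 ± 1.31 CPM (log2 6.25, SE 0.12; n = 4 and 4; edgeR quasi-likelihood, adjusted p = 5.18e-13). Cd1d1 was higher in MZ cells (log2 3.60, SE 0.08), as were the Notch targets Hes5 (log2 4.69, SE 0.10), Dtx1 (log2 3.45, SE 0.09) and Hes1 (log2 2.81, SE 0.06). Notch2 itself was lower in MZ cells (log2 −1.37, SE 0.10). Klf2 stood at 39.3 ± 6.65 in MZ and 193 ± 6.92 in FO cells (log2 −2.30, SE 0.10; edgeR quasi-likelihood, adjusted p = 9.01e-10), and Zfp36l1 at 114 ± 6.25 and 357 ± 19.4 (log2 −1.65, SE 0.06; edgeR quasi-likelihood, adjusted p = 2.03e-11). Genes that, like Zfp36l1, have most of their exon bases under exons of the other strand had a median log2 difference of −1.26 between MZ and FO cells. Zfp36 (log2 −0.98, SE 0.10) and Zfp36l2 (log2 −1.03, SE 0.13) were lower in MZ cells too, and Irf8 was not called (log2 −0.15, SE 0.09; edgeR quasi-likelihood, adjusted p = 0.128). The sort markers differed as the gates require (Cr2, log2 1.60, SE 0.09; Fcer2a, log2 −3.31, SE 0.29), which is no finding. Cell type, library kit, read layout, the floxed Zfp36l1 allele and cre genotype differ together between these groups. No difference here can therefore be assigned to cell type alone.

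MZ identity genes were higher in 19 of 20 cases, the exception being Notch2 (camera, adjusted p = 3.79e-17; adjusted p = 0.0622 with an estimated correlation). FO identity genes were lower in 14 of 16 cases (camera, adjusted p = 2.8e-08; adjusted p = 0.266 with an estimated correlation), among them Cd55 (log2 −2.98, SE 0.08), Ighd for the IgD heavy chain (log2 −2.46, SE 0.10) and the inhibitory receptor gene Btla (log2 −1.96, SE 0.07). The sort marker gene Fcer2a is also among the 14 and was not left out of the test, so part of this list's difference is set by the gates. Ribosomal protein genes were lower in 72 of 75 cases (camera, adjusted p = 1.99e-37; adjusted p = 0.54 with an estimated correlation), such as Rpl21 (log2 −5.28, SE 0.09) and Rps15 (log2 −3.12, SE 0.06), and higher in 2, Rpl13 (log2 0.32, SE 0.06) and Rpl24 (log2 0.40, SE 0.16). Mitochondrially encoded genes were lower in 11 of 12 cases (camera, adjusted p = 3.55e-05; adjusted p = 0.859 with an estimated correlation), such as mt-Atp8 (log2 −4.04, SE 0.07), mt-Nd2 (log2 −2.26, SE 0.09) and mt-Co1 (log2 −1.66, SE 0.08). Rpl24 was not called without control replicates 3 or 5 or FO replicates 4, 7 or 8. The exception among the mitochondrial genes was mt-Nd6, the only protein gene on the other mitochondrial strand (log2 2.51, SE 0.09). The p of each of these 4 lists was smallest in the real split, that of MZ identity by far (2.62e-18, next 4.45e-06). Some list stood as far below its p in all other splits in 1 of the 35 splits for the ribosomal list (the real one). Chance is unlikely there, though this test was chosen after the result was seen. The number of such splits was 2 for MZ identity, 3 for FO identity and 4 for the mitochondrial list. For these, chance is not excluded for how far the list stands apart from other genes; the calls of their members are another matter, as no other split called any gene (0). The number of called lists was 4 of 29, and all 35 splits called at least as many (highest other 14), so chance cannot be excluded for that number.

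Genes of other programmes went both ways, and the balance of several lists turned with an offset for GC content and gene length. Among B cell transcription factors, 11 were higher in MZ cells, such as Nfatc1 (log2 1.38, SE 0.06), and 22 of 41 were lower, such as Bcl6, which drives germinal centre fate (log2 −2.69, SE 0.06), Nfkb1 (log2 −1.85, SE 0.06) and Ikzf3 (log2 −1.57, SE 0.05). With the offset 20 were higher and 15 lower. Of 34 Notch pathway genes, 12 were higher and 17 lower, including the coactivator Maml1 (log2 −2.16, SE 0.07), against 17 higher and 10 lower with the offset. Among migration genes, 19 were higher and 37 of 67 lower, including Rasgrp2 (log2 −2.89, SE 0.06), Arhgef18 (log2 −2.60, SE 0.06) and the integrin gene Itga4 (log2 −2.37, SE 0.07), against 27 higher and 31 lower with the offset. In Toll-like receptor signalling, Tlr3 (log2 3.43, SE 0.14) and Nfkbie (log2 1.19, SE 0.05) were higher, and the DNA sensor Tlr9 (log2 −4.07, SE 0.07) and Tab2 (log2 −2.70, SE 0.06) lower. Of 34 genes of antibody secretion and the unfolded protein response, 19 were higher, such as Pdia4 (log2 2.92, SE 0.09), Mzb1 (log2 1.90, SE 0.08) and Prdm1, which directs plasma cell differentiation (log2 2.69, SE 0.17), and 11 were lower, such as Atf4 (log2 −0.91, SE 0.06).

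Platelet and macrophage markers were higher in the MZ than in the FO libraries: all 11 platelet markers, such as Pf4 (log2 3.99, SE 0.36) and Ppbp, at 5.61 against 0.536 CPM (log2 3.37, SE 0.27), and 14 of 19 macrophage markers, such as Lyz2, at 4.73 against 0.619 (log2 2.93, SE 0.23), and Vcam1 (log2 3.04, SE 0.36). The macrophage gene Adgre1 was lower (log2 −2.56, SE 0.44). These lists were not called as a whole (camera, adjusted p = 0.105 and 0.213). Other markers went both ways: 1 of 6 erythroid markers was higher and 2 were lower, and 3 of 8 dendritic cell markers were higher and 1 was lower. The higher erythroid markers numbered 3 without control replicate 3 or 4 or FO replicate 4 and 2 without FO replicate 3, 7 or 8, and the higher dendritic cell markers 6 without FO replicate 4. Cd93, named in both sort gates, stood at 0.658 ± 0.256 in MZ and 18.9 ± 2.40 in FO libraries (log2 −4.83, SE 0.20; edgeR quasi-likelihood, adjusted p = 1.28e-10).

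In total, 11256 of 13843 tested genes differed between control MZ and FO cells (edgeR quasi-likelihood, adjusted p < 0.05), 5892 higher and 5364 lower in MZ cells. No other split of these 8 libraries called any gene (0), so chance is unlikely for this count. The limits given above for such splits hold here too. The authors' table calls 13082 genes, and 11142 are in both sets. Tested against a fold change of 1.5, 6746 genes remained. Higher in MZ cells were the chemokine scavenger Ackr3 at 127 ± 18.6 against 0.102 CPM (log2 10.23, SE 0.19), Tspan15 (log2 9.36, SE 0.21) and Tnfrsf26, which had no count in FO cells (at least 808-fold). Pseudogenes stood out as well: Rps6-ps4 had no count in FO cells (at least 6956-fold higher in MZ cells), followed by Rps19-ps6 (log2 11.65, SE 0.18), Rps2-ps6 (log2 10.07, SE 0.21) and Ftl1-ps1 (log2 9.38, SE 0.24). Lower in MZ cells were Cacna1i (log2 −8.77, SE 0.16), Ahnak (log2 −6.89, SE 0.24) and Col27a1 (log2 −6.65, SE 0.38).

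Several genes lower in MZ cells share sequence with a gene on the other strand. Med10 (92.8% of exon bases under such exons) and Pdcd2 (100%) had no count in any control MZ library, at least 1745-fold and 1136-fold lower. Pus3 (88.1%) had 1 count there, 5280-fold lower (95% counting interval 948 to 208500), Ilk (89.7%) was nearly absent (log2 −10.70, SE 0.13), and Rpl23a (59.7%) stood at 5.21 ± 0.487 against 890 ± 39.0 CPM (log2 −7.41, SE 0.08).

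Klf2 and Vim, higher in deficient than in control MZ cells, were also higher in FO than in control MZ cells (FO minus control log2 2.30 and 4.61). Over 13386 genes the deficient and FO differences from control barely correlated (Pearson r = 0.0531). Shared control libraries alone give rise to such a correlation: simulated unchanged cells gave a mean r of 0.495 (0.474 to 0.530 over 20 draws). This r cannot be set against the real one, because the simulated cells lacked the large FO differences, whose spread lowers r. The covariance was 0.0223 in the simulation, below the real 0.0355. With the controls divided between the differences, r ran from −0.0263 to 0.0594. Of the 35 splits of the MZ libraries, 14 gave as large a correlation with FO minus all MZ libraries (real 0.0711 in size, highest other 0.152), so chance cannot be excluded.

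**Figure D4:**
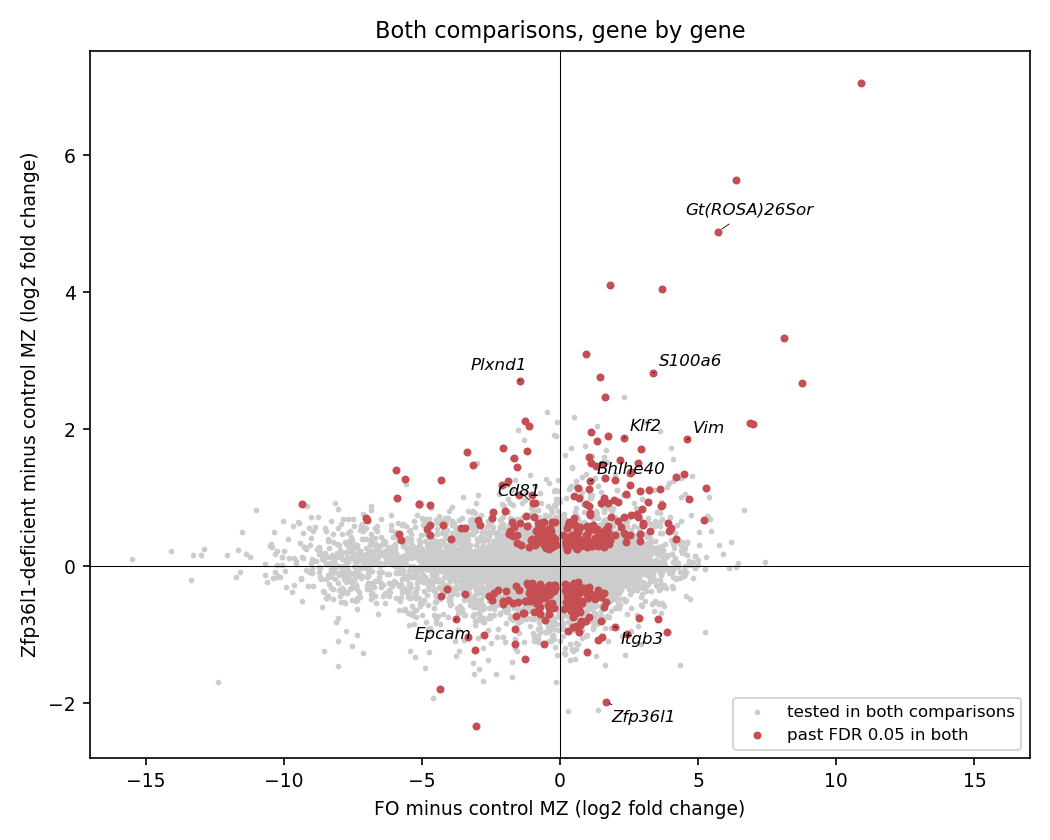
Differences of FO (horizontal) and deficient MZ cells (vertical) from control MZ cells for 13386 genes, as log2 fold changes. Genes called in both comparisons are red.

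Genes that rose in deficient cells and were higher in FO cells numbered 160, against 116 if the calls were independent. Besides Klf2 and Vim these included the calcium-binding gene S100a6 (deficient minus control log2 2.82, FO minus control 3.37) and the sugar transporter gene Slc2a6 (1.71 and 2.95). Gt(ROSA)26Sor (4.884 and 5.725) and Bhlhe40 (1.25 and 1.09), which lies within 20 Mb of it, were among them too. With divided controls the count of genes that were higher in both ran from 48 to 74, against 26.4 to 58.8 if independent. Deficient and FO cells share the floxed allele and carry fewer ERT2cre copies than the controls. An effect of either could make both differences agree, and dividing the controls does not remove it. Genes that rose in deficient cells but were lower in FO cells numbered 107, against 138 if independent, such as Plxnd1 (2.71 and −1.44), Cd81 (0.92 and −0.97) and Gpr171 (0.59 and −1.18). Of the genes that fell in deficient cells, 79 were higher in FO cells, such as Itgb3 (−0.89 and 1.97), Zkscan17 (−0.80 and 0.93) and Tmed10 (−0.58 and 0.32), and 91 were lower, such as Epcam (−0.77 and −3.76) and the protease gene St14 (−0.54 and −1.71). The numbers for independent calls are 75.8 and 89.8. With divided controls, genes that rose in deficient cells but were lower in FO cells numbered 13 to 61, against 31.5 to 68.7 if independent. Genes that fell in deficient cells but were higher in FO cells numbered 12 to 39, against 8.1 to 24.5. Those lower in both numbered 6 to 31, against 9.6 to 28.6.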

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

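Values of each named gene (log2 CPM) and of each library measure were tested for a single replicate far from the other 3 of its group. The rule was set before the data were examined, but some of the genes were named only after their values were seen. A replicate counts as apart where its gap to the nearest other replicate is over 0.829 of the whole range of the group. This held in 22 of 303 sets, and chance alone sets apart about 5% of such sets.

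Control replicate 6 stood apart at 5 genes, with lower Gpr171 (share of the range 0.845), Col27a1 (0.844), Btla (0.866), mt-Nd2 (0.859) and mt-Co1 (0.86). Its share of mitochondrial counts was 2.35% against 2.83% to 2.87% in the other controls (0.933). Control replicate 5 was higher for Tlr3 (0.861), Rrm2 (0.875) and Ccr7 (0.903), and control replicate 4 was lower for Kif11 (0.99) and Trim30a (0.898). Control replicate 3 was higher for Ikzf3 (0.838) and held the only count of Pus3 (1, the whole range). Deficient replicate 2 was higher for Myc (0.848) and lower for S1pr4 (0.882) and E2f2 (0.831). Deficient replicate 7 was higher for Adgre1 (0.907), and deficient replicate 1 was lower for Tlr4 (0.912). FO replicate 4 was higher for Irf8 (0.901), Slc2a6 (0.841) and Gpr171 (0.894), and FO replicate 3 was lower for Mzb1 (0.972).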

How the results depend on the processing

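The alternatives were set before the data were examined, except those on genes near the engineered loci, on genes clear of other genes, on FO minus all MZ libraries and on the region of Gt(ROSA)26Sor. Where a value below moved, the cause was not tested. The 526 changed genes between deficient and control MZ cells became 1057 with DESeq2, 790 with all 12 libraries in 1 fit and 26 (25 higher, 1 lower) when tested against a fold change of 1.5, 500 without genes near the engineered loci, and 257 to 506 without 1 library, which also lowers the power of the test. The count fell over 1.5 times without control replicate 3 (309), 4 (257) or 6 (311) or deficient replicate 8 (299). Of 74 named genes called there, 12 kept the call in every setting and 22 lost it without some library. Others, such as Zfp36l2, Cd1d1, Irf4 and Myc, lost it only in the stricter test against a fold change of 1.5. Zfp36l1 kept its call throughout (log2 −2.11 to −1.86).

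The 11256 genes between control MZ and FO cells became 6746 when tested against a fold change of 1.5, 6173 among protein-coding genes clear of other genes, of which fewer were tested, and 11160 to 11483 without 1 library. With upper-quartile factors 58.4% of them were higher in MZ cells, against 52.3%. Of 82 named genes called there, 69 kept the call in every setting and 3 (Rpl24, Efnb1 and Eif2s3y) lost it without some library. With the GC content and length offset, 10183 of the 11256 genes stayed called, 512 of them with the opposite sign. Among named genes, the sign changed for Kdm5d (log2 0.0468) and Irf4 (log2 0.149). With the replicate number as a block, 9882 genes were called, or 9835 with the offset too, where 429 genes called in both fits and, among named genes, Kdm5d (0.0477), Eif2s3y (−0.0659) and Irf4 (0.158) changed sign. Only numbers 3 and 4 are shared, so both block fits take the group difference from replicates 3 and 4 alone. They do not test the calls over all 8 libraries. The deviations of the libraries with number 3 and with number 4 correlate at −0.066 and −0.143, so the numbers do not pair the samples. No paired analysis was possible because deficient and control replicates share no number.

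Of the called gene lists, 0 of 9 and 0 of 4 remained with an estimated correlation between genes, and without 1 library 12 to 16 and 4 were called; the first count was 14 without control replicate 6 and 16 without deficient replicate 7 or 8. In control MZ against FO cells the median of the Notch, transcription factor, migration, survival, oxidative phosphorylation and heat shock lists changed sign with the GC content and length offset, that of immediate-early genes with upper-quartile factors, and that of BCR signalling with both. The correlation of 0.0531 between the contrasts was 0.0922 with the GC content and length offset, 0.0978 for genes clear of other genes, and 0.0362 to 0.112 without 1 library (0.0798, 0.0772 and 0.112 without control replicate 3, 4 or 5). It was 0.01, −0.0161, −0.0102 and −0.0263 in 4 of the 6 divisions of the controls and −0.0711 against FO minus all MZ libraries. For the AU-rich motif, the odds ratio was 1.24 for the ATTTA pentamer (Fisher's exact p = 0.12), 1.21 for a nonamer (exact p = 0.376) and 1.08 for genes that fell (exact p = 0.637). The odds ratio near Zfp36l1 (0.977) was 2.56 around Gt(ROSA)26Sor instead. Recovery of 58.2% of simulated 1.5-fold changes shows what this depth and spread can miss.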

Other observations

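The tests for FO cells in the sort, for the Gt(ROSA)26Sor locus, for exons of the other strand, for GC content and length, and for the splits of single gene lists were chosen after the result was seen; the other tests were set before. In control MZ cells, 16 of 35 interferon response genes were higher than in FO cells and 3 were lower, Parp14 (log2 −1.52, SE 0.15), Eif2ak2 (log2 −1.19, SE 0.17) and Trim30a (log2 −0.57, SE 0.16) (camera, adjusted p = 0.476). Of 12 germinal centre markers, 2 were higher, Fas (log2 0.76, SE 0.16) and Efnb1 (log2 0.34, SE 0.14), and 8 lower (camera, adjusted p = 0.213), and of 6 transitional B cell markers 1 was higher, Myb (log2 0.96, SE 0.22), and 5 lower, Cd93 among them (camera, adjusted p = 0.228). Of 39 cell cycle genes, 15 were higher and 7 lower in MZ cells (camera, adjusted p = 0.629). Efnb1 was not called without control replicates 4 or 5 or any FO replicate. All 12 libraries held Ddx3y, a gene of the Y chromosome (166 to 258 CPM), with at most 0.398 of Xist, which is made from the inactive X chromosome.

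The first pattern is that Klf2, Vim and some other FO genes rose in deficient MZ cells. FO cells in the sorted sample are 1 explanation: Klf2 alone would need an FO share of 0.668, but 13 other FO identity genes imply a median share of 0.0574 (95% interval 0.0074 to 0.0844), and 0 of them reach the share of Klf2, which argues against it for Klf2. These shares assume that both kits give the same ratio of FO to MZ levels, and a share of a few percent stays open for smaller rises such as that of Cd55. Chance is unlikely for the 526 calls (1 of 35 splits of the libraries, the real one and the smallest share possible). It stays open for the FO identity list (7 of 35, real value 2.39 and highest other 7.74 on a log10 scale), the cell cycle list (5 of 35), the number of lists (11 of 35) and the correlation with the FO difference (14 of 35). Loss of Zfp36l1 and the number of ERT2cre copies, which differ together between the groups, both stay open.

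The second pattern is the excess of changed genes around Gt(ROSA)26Sor, with Plxnd1, Il5ra and Srgap3 among them. Gt(ROSA)26Sor stood at 0.318 to 0.834 CPM in control MZ (ERT2cre/ERT2cre), 14.2 to 19.4 in deficient MZ (ERT2cre/+) and 27.6 to 33.7 in FO libraries (cre-), with a deficient to FO ratio of 0.552. As a hypothesis, ERT2cre may sit at this locus, so that the groups carry 0, 1 and 2 intact alleles, and cre copies or flanking DNA of another strain could then change the neighbours. A family of like-named genes does not account for the excess, since at most 1 of the 17 genes has the same first 4 letters in its symbol. Symbols do not show whether neighbours are related or controlled together, so clustered genes of 1 kind stay open. Of the 13 neighbours that differ between FO and control MZ cells, 8 do so in the same direction as in deficient cells and 5 in the opposite one (exact binomial p = 0.581), so the part of cre copies or flanking DNA stays open, as does that of Zfp36l1.

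The third pattern is the large differences of single genes between control MZ and FO libraries, such as Med10, Ilk and Rpl21. Reads not assigned where exons of the other strand overlap could account for part of them: genes with over 0.5 of their exon bases under such exons had a median log2 difference −1.34 from those with none (95% interval −1.95 to −0.72; 101 and 8169 genes). Reads shared with processed pseudogenes do not account for low ribosomal protein genes, since with all pseudogene counts added the share reached 3.46% in control MZ against at least 7.01% in FO libraries, though reads discarded for matching several places stay open. Of 1632 called genes at least 8-fold apart, 90.6% stayed so in the same direction with the GC content and length offset (95% interval 89.0% to 91.9%). Among all calls, 512 genes changed sign with it. A smooth trend with GC content and length thus does not account for most of these large differences. The offset removes only what genes of like GC content and length share, so such effects of the kits at single genes stay open. Chance is unlikely for the 11256 calls (1 of 35 splits, the smallest share possible) but stays open for the number of lists (35 of 35), and cell type itself was not tested apart from the kit.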
